A study of Saccharomyces cerevisiae with 40 samples.

How the data were processed

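RNA abundance was measured in Saccharomyces cerevisiae on 40 Affymetrix yeast arrays. Per the labels, the host strain carried a disruption of NMD2 by HIS3. It held either a URA3 plasmid with NMD2 under the GAL1 promoter (GAL-NMD2) or the empty vector (nmd2D). Each strain was sampled at 0, 10, 20, 40 and 60 min with 4 replicates, described in the series design as independent, which gave 10 groups of 4 arrays. The labels conflict on the medium: the series design describes raffinose medium with galactose added at the start of the course, whereas the growth protocol of each sample names galactose. The order of times follows the sample labels.

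Per the labels' protocols, total RNA was extracted with hot phenol and 6 ug was used to make biotin-labelled cRNA. Per the submitters' processing notes, the deposited signal intensity of each probe set came from MAS5; its version and settings are not given in the sources used here. The deposited intensities are linear, with no missing value, and reach 14594.5. The mean of the middle 96% of values lay between 250.155 and 250.222 on every array, so the authors' values carry a scaling of each array to one trimmed mean. Such scaling sets no individual level, but it makes every value relative to the bright part of its array. Detection calls were not used here, and the number of arrays limits the precision. Median signal per array ranged from 61.2 to 86, and the ratio of the 3-prime to the 5-prime actin control probe set from 1.38 to 2.95. No arrays were identical, and correlations within groups ranged from 0.939 to 0.984.

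The table held 9335 probe sets, of which 60 were controls. Of the other 9275, 6504 had 1 gene symbol in the platform annotation, 328 had several and 2443 had none; no gene was named from the latter kinds. All 6504 symbols were matched through their gene identifiers to the R64 gene table, which was used for names and for gene order. No genome or probe sequence was used, so positions are not given and cross-hybridization between related genes was not examined.

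Values were transformed as log2(intensity + 16), and probe sets whose mean was below the 20th percentile were left out, leaving 7420. Folds are on this scale and understate changes of dim probe sets. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 10 groups over all 40 arrays (lmFit, eBayes with trend). Benjamini-Hochberg adjusted p under 0.05 within a comparison was called. The interaction is the change from 0 min in GAL-NMD2 minus that in nmd2D. The other comparisons were the strains at 0 and 60 min and each strain's response at 60 min. Gene lists, with 1 probe set per gene, were tested by camera with a preset correlation of 0.01 and with an estimated one.

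The rule for named genes, the comparisons and 26 gene lists were fixed before the data were examined. NMD2, HIS3, URA3 and the galactose genes were checks. Otherwise a named gene had a probe set of 1 gene, a call, and no overlap between the 4 values of either side (for interactions, the changes per replicate number). Of these, the 15 largest falls and 10 largest rises of the interaction at 60 min were taken, 5 of each at 10 and 20 min and for the strains at 0 min, and 10 of each for the nmd2D response. Up to 4 members per list with the largest change were also allowed, and any member of the list of substrates of nonsense-mediated decay. Genes outside this rule are said to be chosen after their values were seen.

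Replicate numbers come from the labels, which do not say that a number marks a shared day or batch. Deviations from group means correlated between same-numbered arrays in 51 of 52 pairs with r above 0.1; the exception, r = 0.068, was replicate 2 of the strains at 20 min. The mean r was 0.65 for the same number and strain, 0.51 for the same number in the other strain and -0.20 for other numbers. Subtracting group means pushes the last value below 0 by itself, so it is no separate evidence of pairing. The replicate block and the changes per replicate number took the numbers to pair the samples, and the main fit did not. This pairing was also applied to the strains at 20 min. Only replicate 2 was weak there: replicates 1, 3 and 4 had r = 0.56, 0.57 and 0.50. The GAL-NMD2 array of replicate 2 at 20 min also had the lowest r within a strain, 0.18 with its 0 min array. Its median signal was 84.3, against 63.6 to 67.9 in the other GAL-NMD2 arrays at 20 min. It was kept in the main fit. Values with the replicate number as a block stand beside results that it changes.

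Data were simulated over 7420 probe sets, with 200 changed at the interaction at 60 min. Each probe set had 1 mean in all groups, its real replicate effects shared by both strains, and independent normal residuals of the real spread. The fit recovered 4% of 1.5-fold, 32% of 2-fold, 82% of 3-fold and 94% of 4-fold changes, with 0 false calls. With the replicate block it recovered 28%, 72%, 98% and 98%, with 4 false calls. The simulated data followed the model of that block and held no further correlation within a culture, so these rates favour the block. Alternatives were other pseudocounts, filters and scalings, the replicate block, culture as a random block, no trend, only the groups compared, a minimum fold of 1.5, and leaving out each culture. Chosen after seeing the data were the replicate block combined with a random culture block, the block without each replicate number, and loess normalization.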

Results

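The series asked how expression changes when NMD2, a factor of nonsense-mediated mRNA decay (NMD), is switched on in cells that lack it. The 40 arrays covered a strain with NMD2 under the galactose-inducible GAL1 promoter (GAL-NMD2) and an empty-vector control (nmd2D), at 0, 10, 20, 40 and 60 min after galactose, with n = 4 per group. Values are MAS5 signal intensities and errors are SD between replicates unless stated as standard errors (SE).

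The strains were checked first. NMD2 rose in GAL-NMD2 from 1038 ± 177 at 0 min to 1654 ± 212 at 60 min, against 895 ± 34.9 and 889 ± 132 in nmd2D (interaction log2 0.69, SE 0.21, limma adjusted p = 0.0485). The probe set thus read signal in the disrupted strain, so it is a limited check of the deletion, and the call was lost in 11 of 19 other ways of processing or selecting the arrays. URA3, the plasmid marker, read 1305 ± 969 in nmd2D and 317 ± 119 in GAL-NMD2 at 0 min (log2 -1.82, SE 0.51); this was not called without the replicate block and was called with it (adjusted p = 0.0309). HIS3, at the brighter of its probe sets, read 1655 ± 495 and 1655 ± 528 at 0 min in the GAL-NMD2 and nmd2D strains.

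Galactose genes rose in nmd2D. GAL1 (galactokinase) went from 85.9 ± 14.2 to 3155 ± 658 at 60 min, a 30.8-fold rise (log2 4.95, SE 0.26, limma adjusted p = 1.27e-16). GAL2 (the galactose permease) rose 30.0-fold, GAL10 27.1-fold and GAL7 15.3-fold, and GAL3 and GAL80, regulators of the pathway, 4.34-fold and 2.82-fold. Of 13 galactose genes tested, 8 rose over all genes tested, 11 when adjusted over the list alone and 11 with the replicate block. Their list median was 1.32 (adjusted p = 9.73e-11 with an estimated correlation). FUR4 (the uracil permease), a member of that list, rose 2.49-fold. Outside the list SDD1, NCA3 and RIO1 also rose, 5.15-fold, 2.83-fold and 2.61-fold. In GAL-NMD2 the change of GAL1 was log2 4.90, and no galactose gene had a called interaction at 60 min (list median 0.04).

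Few other genes responded in nmd2D. STL1 (a glycerol transporter) fell from 119 ± 41.2 to 27.5 ± 19.2 (log2 -1.70, SE 0.28, adjusted p = 0.000539), and TPS2, HXK1, GPD1 and CYR1 (adenylate cyclase) fell by log2 1.21, 1.09, 1.08 and 0.84. TPS2 and HXK1 belong to the environmental stress list. In that list 2 of 31 members fell over all genes, 12 adjusted over the list alone and 14 with the replicate block (median -0.53, adjusted p = 0.0439 with an estimated correlation). Ribosome biogenesis genes (median 0.36) and gluconeogenesis and glyoxylate genes (median -0.52) were called by camera with the preset correlation; adjusted p = 0.203 and adjusted p = 0.154 with an estimated correlation. In the blocked fit 2 biogenesis genes, 1 G1 and S phase gene and 1 haploid mating gene rose, and 3 gluconeogenesis and glyoxylate genes and 2 respiration genes fell. Heat shock genes (median 0.11) and G1 and S phase genes (median 0.22) were also called with the preset only; adjusted p = 0.688 and adjusted p = 0.721 with an estimated correlation. Over all probe sets 6 fell and 13 rose. The replicate block gave 80 falls and 67 rises, and without nmd2D replicate 3 the total was 11. Fitting only the 8 arrays compared gave 0 falls and 10 rises, so all the falls named here lost their call, as did the rises of GAL3, RIO1 and FUR4.

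Before galactose 1 probe set was called between the strains. PTC7 (a mitochondrial protein phosphatase) read 745 ± 143 in GAL-NMD2 and 150 ± 28.9 in nmd2D (log2 2.19, SE 0.24, limma adjusted p = 5.07e-07), higher in 4 of 4 replicates. Pyrimidine synthesis genes were lower in GAL-NMD2 as a list (8 genes, median -0.24, adjusted p = 0.0078 with an estimated correlation; 0 called over all genes, 2 adjusted over the list alone and 1 with the replicate block). Ribosomal protein (median 0.12), glycolysis (median 0.10) and mitotic genes (median -0.24) were called with the preset correlation only; adjusted p = 0.628, adjusted p = 0.630 and adjusted p = 0.630 with an estimated correlation. With the replicate block the preset correlation also called galactose genes (median 0.12, adjusted p = 0.0438), general control genes (median 0.05, adjusted p = 0.0274) and gluconeogenesis and glyoxylate genes (median -0.27, adjusted p = 0.0197); with an estimated correlation these had adjusted p = 0.563, adjusted p = 0.563 and adjusted p = 0.576. Over all probe sets the replicate block gave 3 lower and 8 higher, and without GAL-NMD2 replicate 2 the total was 16. A gene whose replicates disagreed could miss the call. HUG1, chosen after its values were seen, read 35.5 in GAL-NMD2 replicate 2 and 3470 to 4422 in the other GAL-NMD2 replicates, and was not called.

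The galactose response then diverged between the strains. At 10 min limma called 0 probe sets (59 at an unadjusted p under 0.05, and 0 with the replicate block, 261 unadjusted). Chance alone would put a share of 0.05 of the 7420 probe sets under that p. Both counts were below it, as were those without the block at 20 min (117) and for the strains at 0 min (147). The fit was thus conservative there, and few or 0 calls do not show that nothing changed. At 20 min RRT13 alone was called for the interaction. It read 238 ± 47.5 in GAL-NMD2 and 471 ± 13.5 in nmd2D (interaction log2 -0.99, SE 0.18, limma adjusted p = 0.0209), and the call was lost without any one of 7 of the 8 cultures. Other comparisons at 20 min, outside those fixed beforehand, called more without the block. Between the strains 35 probe sets were lower and 2 higher in GAL-NMD2. From 0 to 20 min 23 fell and 10 rose in GAL-NMD2, against 1 and 10 in nmd2D. At 40 min 111 probe sets were lower and 0 higher, and at 60 min 290 were lower and 1, NMD2, higher. The total at 40 min was 55 without nmd2D replicate 2, 59 without GAL-NMD2 replicate 2 and 60 without nmd2D replicate 3, and centring each array on its median gave 66 lower and 2 higher. With the replicate block 493 were lower and 25 higher at 40 min, and 720 lower and 6 higher at 60 min. The 290 probe sets had a median strain difference of log2 -0.03 at 10 min, -0.45 at 20 min, -0.997 at 40 min and -1.18 at 60 min; they were chosen on the 60 min values, so their size there is overstated.

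**Figure D1:**
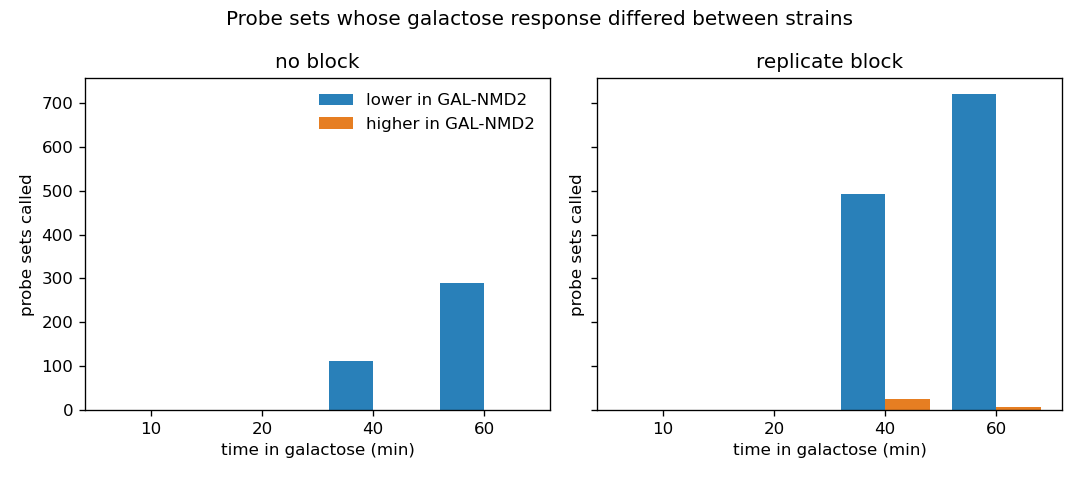
Number of probe sets called for the interaction (y axis) at each time in galactose in minutes (x axis), lower (blue) or higher (orange) in GAL-NMD2, without a block (left) and with the replicate block (right). At 60 min 290 were lower and 1 higher without a block, and 720 and 6 with it.

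At 60 min the largest fall among named genes was that of ADE2, an enzyme of purine synthesis. It dropped from 947 ± 86.1 to 162 ± 26.6 in GAL-NMD2 and read 964 ± 225 and 1013 ± 136 in nmd2D (interaction log2 -2.53, SE 0.28, limma adjusted p = 2.02e-07). PET18 fell by log2 2.28, YIR043C by 2.21, RRT13 by 2.09, YNL162W-A by 2.08 and ISC10 by 2.07. PPT2 (a phosphopantetheine transferase), PAU7, SHH4 and DAL5 (an allantoate permease) fell by log2 1.99, 1.84, 1.84 and 1.82. YEL073C, STN1, JLP1, HRT1 and PEX35 completed the rule's 15, with falls of log2 1.81, 1.79, 1.79, 1.78 and 1.76. In all, 200 named genes were lower, and 191 of the 290 probe sets by 2-fold or more; 87 had no gene symbol of their own. Centring each array on its median lowered the count to 124 lower and 2 higher, and quantile normalization to 167 and 1. The total was 184 without GAL-NMD2 replicate 3, 160 without nmd2D replicate 2 and 173 without nmd2D replicate 3.

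**Figure D2:**
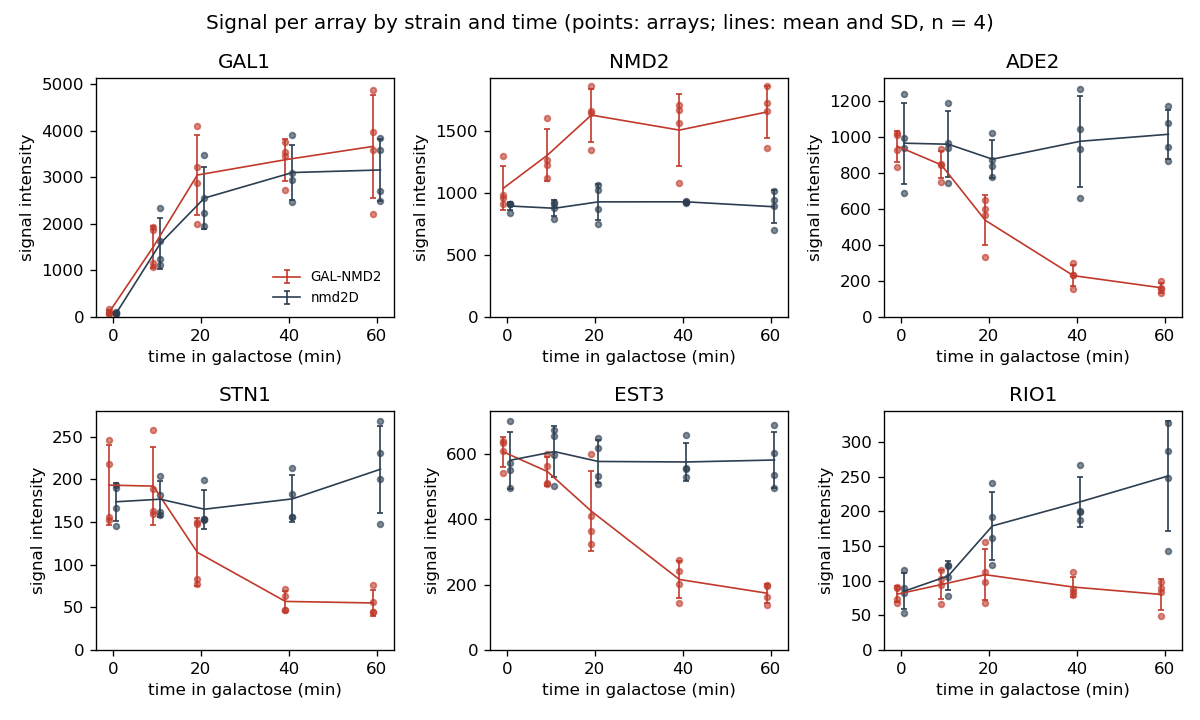
Signal intensity (y axis, linear) against time in galactose in minutes (x axis) for GAL1, NMD2, ADE2, STN1, EST3 and RIO1; points are arrays, offset sideways by strain, and lines join means with SD bars (n = 4). ADE2 fell from 947 to 162 in GAL-NMD2 and read 1013 in nmd2D at 60 min, while GAL1 rose in both strains.

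Transcripts listed beforehand as NMD substrates fell as a group. Of 20 tested, 5 fell over all genes, 7 adjusted over the list alone and 10 with the replicate block. EST3, a telomerase subunit, dropped from 606 ± 44.9 to 174 ± 28.3 in GAL-NMD2 (interaction log2 -1.73, SE 0.24, adjusted p = 1.01e-05). The telomere-capping genes STN1 and TEN1 fell by log2 1.79 and 1.36, the telomerase subunit EST1 by 1.20 and COX19 by 1.52. The list median was -0.59 (camera adjusted p = 1.60e-05 with an estimated correlation), against 0.06 at 10 min, -0.22 at 20 min and -0.39 at 40 min. CPA1 read 1666 ± 223 in GAL-NMD2 and 3236 ± 714 in nmd2D at 60 min (log2 -0.92, SE 0.45, adjusted p = 0.470; with the replicate block, adjusted p = 7.91e-05). REV7 was below the filter and was not tested.

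**Figure D3:**
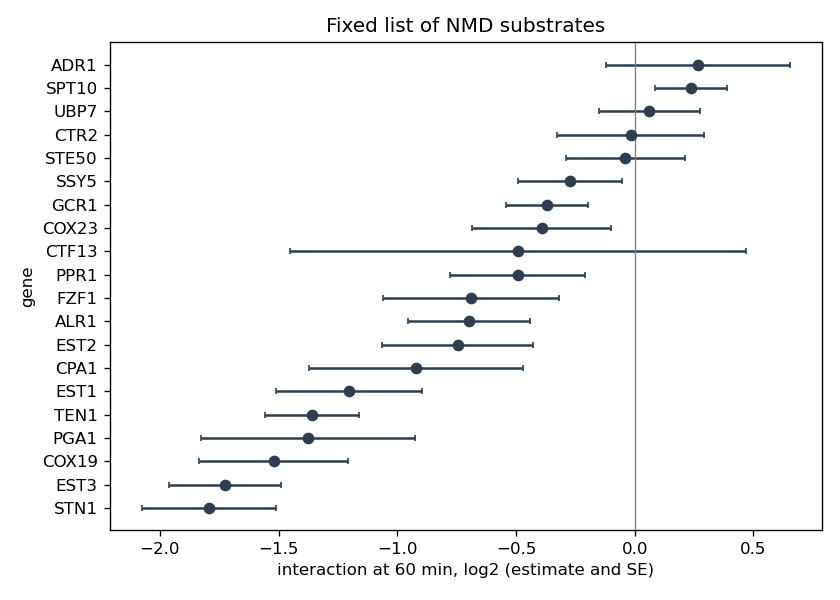
Interaction at 60 min on the log2 scale (x axis; points are estimates, bars SE) for the 20 tested members of the list of NMD substrates (y axis). STN1 and EST3, at -1.79 and -1.73, lie lowest.

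Among the other lists, 6 of 18 nitrogen catabolite genes fell, among them DAL5, DUR3 (a urea permease, log2 -1.36), CAN1 (the arginine permease, -1.37) and DAL2 (-1.32). The list median was -0.25 (adjusted p = 0.0454 with an estimated correlation; with the replicate block, adjusted p = 0.187). Of 13 meiosis and sporulation genes 3 fell, REC104, IME2 and SPS100, by log2 1.05, 0.89 and 0.79 (median -0.59, adjusted p = 0.0224 with an estimated correlation; with the replicate block, adjusted p = 0.0764). Telomere and silencing genes (16 tested, median -0.35) had 4 falls, all of them NMD list members, and the call was lost with an estimated correlation (adjusted p = 0.125). Of 20 decay factors, NMD4, which binds the NMD helicase, and EBS1 fell by log2 1.72 and 0.84, with a list median of 0.11. Falls were also called for MAL11 and MAL31 (maltose genes, log2 -1.69 and -1.16; list median -0.03), FRE3 and ARN2 (iron uptake, -1.55 and -1.38; list median -0.15, with 2 of 24 metal genes lower, 4 adjusted over the list alone and 8 with the replicate block), PCK1 (gluconeogenesis, -1.33; list median 0.10), SSA4 (a chaperone, -0.80; list median 0.08) and FUS2 (mating, -0.94; list median -0.11). Adjusted over the list alone, 7 nitrogen catabolite and 4 meiosis genes fell. The replicate block gave 7 falls among nitrogen catabolite genes, 4 among meiosis genes, 5 among telomere genes and 2 among heat shock genes.

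Without the replicate block no member of the remaining lists was called for the interaction at 60 min, and none of these lists was called by camera; adjusted over the list alone, 1 methionine gene fell. The medians were 0.13 for pyrimidine synthesis, -0.04 for arginine, 0.09 for amino acid general control, -0.08 for methionine, 0.04 for ribosomal proteins and 0.08 for ribosome biogenesis. They were 0.16 for stress genes, 0.17 for the tricarboxylic acid cycle, 0.08 for respiration and 0.06 for glycolysis. They were 0.13 for G1 and S phase genes, 0.01 for mitotic genes, 0.13 for histones, and -0.05 and -0.31 for MATa and MATalpha genes. In the blocked fit single members were called lower in the pyrimidine, arginine, methionine, glycolysis and MATa lists and 1 higher in respiration, and the general control list was called with the preset correlation (adjusted p = 0.0288; adjusted p = 0.470 with an estimated correlation). Median and test differed in sign for methionine and for gluconeogenesis, and mean and median for decay factors, pyrimidine synthesis, gluconeogenesis and mitotic genes.

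Compared directly at 60 min, 885 probe sets were lower and 32 higher in GAL-NMD2 than in nmd2D, and within GAL-NMD2 766 fell and 88 rose between 0 and 60 min. ADE2, RRT13 and EST3 were among those lower. With the replicate block these became 1489 and 156, and 1397 and 357. The direction split depended on scaling: with each array centred on its median, 467 were lower and 440 higher between strains, and 495 fell and 328 rose within GAL-NMD2. With quantile normalization the numbers were 517 and 83, and 536 and 217. Median signal per array averaged 65.6 ± 3.74 in GAL-NMD2 and 81.7 ± 3.18 in nmd2D at 60 min, and centring moved the median interaction of all probe sets from -0.01 to 0.16.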

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

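The splits of the samples and the tests of damage genes and of FSH3 and YLR345W were planned before their results were seen. The tests of loess correction, PTC7, NMD2 in replicate 2, the ADE and TRP genes and CAN1 were chosen only after the patterns were seen. Median centring, used to test scaling, and the test of the NMD list were fixed beforehand and set against the pattern only after. The galactose response differed between strains by a test of the difference at 20, 40 and 60 min, with 1, 111 and 291 probe sets. Of the 35 splits of the 8 cultures into 4 and 4, only the real one (1 of 35) reached 111 or 291, and the highest other gave 0. Every other split mixes the strains, which adds any strain difference to the spread and lowers its calls. The splits also ignore the pairing by number, so they do not exclude chance at 40 and 60 min. At 20 min 2 of 35 splits reached 1, the highest other giving 1, so chance cannot be excluded there. At 10 min 35 of 35 gave 0, the real one among them. Every split reaches 0 calls by definition, so the splits decide nothing at 10 min. For the strains at 60 min 1 of 35 splits reached 917 and the highest other gave 319. At 0 min 6 of 35 reached 1, and the split of replicates 1 and 3 of both strains from the rest gave 365, which points to a structure of the samples by replicate number. At 0 min that split also parted the arrays by the actin 3-prime to 5-prime ratio, 2.10 to 2.95 against 1.44 to 1.81. At 60 min, where the same split gave 319, it did not: GAL-NMD2 replicate 1 read 1.60 and replicate 4 read 1.67. Whether the ratio is behind the structure was not tested. Splits of the 8 arrays gave 1 of 35 for the nmd2D response (19, highest other 14) and 1 of 35 for the GAL-NMD2 response (854, highest other 8). All these splits ignore the pairing. The 8 splits that part all same-numbered pairs are too few for a share under 0.05; with the replicate block the real one gave 518 calls for the interaction at 40 min and 726 at 60 min, the highest other 0 at both, 1645 for the strains at 60 min (highest other 3), 147 for the nmd2D response (0) and 1754 for the GAL-NMD2 response (30).

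Falls far outnumbered rises in the interaction at 60 min. Scaling of whole arrays as the whole cause is argued against: after centring each array on its median 98.4% of 126 calls were still lower, although fewer were called. The median change of all probe sets drifted with signal, from -0.07 in the dimmest of 5 classes to 0.09 in the brightest. Loess correction of each array brought the medians to between 0.02 and 0.08 and left 99.5% of 211 calls lower, which argues against a signal-dependent compression as the whole cause. The list of NMD substrates fixed beforehand fell against other genes (adjusted p = 1.60e-05 with an estimated correlation). Falls of NMD substrates on NMD2 expression are a candidate explanation; indirect effects were not tested.

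In genes chosen after their values were seen, GAL-NMD2 replicate 2 lay apart from the other GAL-NMD2 replicates. For HUG1 at 0 min it read like nmd2D, and the other GAL-NMD2 replicates were the ones that differed from nmd2D. HUG1, a regulator of ribonucleotide reductase, read 35.5 there at 0 min against 3470 to 4422 in the other GAL-NMD2 replicates and at most 44.3 in nmd2D, and 33.4 against 2951 to 4621 at 60 min. RNR2 read 1522 against 3317 to 3820 at 0 min, and RFX1, the repressor of these genes, 57.1 against 194 to 235 at 60 min. That its arrays at 10 to 60 min came from nmd2D is argued against by NMD2, which lay on average 0.68 log2 (SE 0.10 over the 4 times) above the highest nmd2D array. For the 0 min array, PTC7 lay 2.12 log2 above the highest nmd2D array, which argues against an nmd2D origin of that array. PTC7 was chosen for lying apart between the strains there, but it was also called without GAL-NMD2 replicate 2. This rests on 1 gene. An exchange with a sample from outside was not tested. A general DNA damage response of 1 log2 or more, the bar set beforehand, is argued against by 7 damage genes. Their median strain difference plus 2 SE, taken over genes and not cultures, was at most 0.264 in any replicate number at 0 min. A weaker response is not excluded. Release of Rfx1 repression stays open: of 10 combinations of FSH3 and YLR345W with time, replicate 2 was lowest in 8, short of the 9 set beforehand and above the 4 that would have counted against it. These combinations read the same cultures repeatedly, so they are not 10 separate tests.

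ADE2 and TRP1 (chosen after its values were seen) fell in GAL-NMD2 at 60 min, TRP1 from 428 ± 109 to 141 ± 69.1 (interaction log2 -1.56, SE 0.40, limma adjusted p = 0.0172). Repression of both pathways is argued against, since 13 other ADE and TRP genes had a median of 0.21. A candidate explanation is that the strain carries nonsense alleles of ADE2, TRP1 and CAN1, as some laboratory strains do. CAN1 fell too (log2 -1.37), but the labels do not give the genotype and CAN1 is also a nitrogen catabolite gene, so this cannot be told apart from other causes.

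Other values stood apart by the gap to the nearest of the 4 arrays of a group; 16 of 320 groups did, 5 of them in GAL-NMD2 replicate 2 and 6 in nmd2D replicate 1. Chance flags about 1 in 20 groups, but the 320 hold genes added because their values stood apart, and the same cultures recur, so the share is no test. Without genes named only after their values were seen it was 11 of 244 groups, 1 in GAL-NMD2 replicate 2 and 6 in nmd2D replicate 1. The rule weighs a gap against the spread of the group, so small differences can be flagged. In nmd2D replicate 1, NMD2 read 842.6 at 0 min (908.9 to 914.3 in the other replicates) and PEX35 210.1 at 60 min (148.2 to 153.1). GPD1 read 1380.8 at 0 min (2372.9 to 2617.3) and 600.8 at 60 min (1166.8 to 1230.7). CPA1 read 1798.8 at 0 min (3319.9 to 3649.4) and 2170.6 at 60 min (3516.1 to 3692.2). CPA1 read 1711.3 (3479.1 to 3676 in the others) in GAL-NMD2 replicate 1 at 0 min. OPT2, chosen after its values were seen, read 287.8 there at 60 min against 24.7 to 30.5 in the other replicates. HXK1 read 2053.8 in GAL-NMD2 replicate 4 at 60 min (1242.4 to 1290.4 in the others) and PPR1 94.3 in replicate 2 (61.2 to 64.6). NCA3 read 131.3 in nmd2D replicate 3 (233 to 251.6 in the others) and SSY5 98.3 in replicate 2 (120.8 to 123.9) at 60 min. RIO1 rose in nmd2D (85.0 to 251) and not in GAL-NMD2 (80.7 to 80.2), an interaction of log2 -1.42 (SE 0.33, limma adjusted p = 0.00772).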

How the results depend on the processing

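The combination of the replicate block with a random culture block, the block without each replicate number, and loess normalization were chosen after seeing the data. Under every alternative run, the interaction at 10 min stayed at 0 calls, and over 94% of calls in the interactions at 40 and 60 min were lower except with culture as a random block or both blocks at 40 min. With the replicate block the calls were 518 for the interaction at 40 min, 726 at 60 min, 11 for the strains at 0 min, 1645 at 60 min, 147 for the nmd2D response and 1754 for the GAL-NMD2 response; all calls made without the block were kept. With culture as a random block the calls were 3 for the interaction at 20 min, 610 at 40 min, 800 at 60 min, 11 for the strains at 0 min, 178 for the nmd2D response and 1931 for the GAL-NMD2 response. With both blocks these were 5, 642, 845, 20, 186 and 1984, and 1556 for the strains at 60 min. Camera was not run with a random block. Median centring gave 0, 68 and 126 calls for the interactions at 20, 40 and 60 min, quantile normalization 168 for the interaction and 600 for the strains at 60 min, and the 50th percentile filter 581 for the strains at 60 min, where fewer probe sets were tested; that filter left no meiosis gene. Fitting only the groups compared, with fewer arrays, gave 0 for the interaction at 20 min, 56 at 40 min, 10 for the nmd2D response and 523 for the GAL-NMD2 response. For the scalings the cause was not tested. Leaving out 1 culture gave 0 to 1 calls for the interaction at 20 min, 55 to 109 at 40 min, 160 to 242 at 60 min, 1 to 16 for the strains at 0 min, 736 to 946 at 60 min, 11 to 23 for the nmd2D response, 570 to 900 for the GAL-NMD2 response and 4 to 7 gene lists for the interaction at 60 min. Without replicate 1, 2, 3 or 4 in turn, the replicate block gave 0, 0, 1 and 0 calls for the interaction at 20 min, 332, 270, 256 and 376 at 40 min, 581, 527, 431 and 610 at 60 min, 1, 25, 1 and 1 for the strains at 0 min, 1487, 1526, 1174 and 1314 at 60 min, 58, 108, 55 and 56 for the nmd2D response, 1403, 1478, 1223 and 1531 for the GAL-NMD2 response, and 6, 6, 4 and 8 lists. Of 6798 values of 274 gene results, 187 lost the call, 179 gained it and 0 reversed. Of 1791 list values, 18 lost and 58 gained it, and 5 reversed (a change of sign with a call in either fit), all for the strains at 0 min: glycolysis to -0.038 with quantile normalization and to -0.023 with loess normalization, ribosome biogenesis to 0.107 without GAL-NMD2 replicate 4 (-0.139 to 0.107 without any 1 culture), and MATa genes to 0.018 without GAL-NMD2 replicate 3 (-0.016 to 0.061 without any 1 culture) and to 0.088 with the block and without replicate 3. Low signal limits dim genes: 20% of probe sets, with a mean signal below 10.98, were not tested.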

Other observations

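Tests of chromosome ends, and of neighbours of galactose genes with left-out genes added back, were chosen after the result was seen; the test of the other neighbours was not. Genes near chromosome ends were frequent among the falls. Of 176 tested genes among the outermost 10 of each chromosome end, 34 (19.3%) were lower in the interaction at 60 min, against 163 of 5073 others (3.21%). The odds ratio was 7.21 (95% interval 4.65 to 10.9, Fisher's exact test, two-sided p = 5.43e-16), and 7.53 (4.99 to 11.4) within 5 classes of signal. Why they fell was not tested. Genes are not independent replicates, and near-identical subtelomeric copies can share probe sets, which was not examined.

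Some changes in galactose differed between the strains, in genes chosen after their values were seen. SUR7, next to GAL80 in gene order, went from 1798 ± 416 to 730 ± 283 in nmd2D and from 1962 ± 584 to 1595 ± 386 in GAL-NMD2 (interaction log2 1.08, limma adjusted p = 0.344; with the replicate block, adjusted p = 0.00921). RIO1 lies next to GCY1, another galactose gene, and TRP1, also a neighbour of a galactose gene, fell (log2 -1.56). Whether neighbours of galactose genes respond as a class was tested on 14 neighbours, leaving out these 3 because their values had been seen. The mean absolute interaction of the 14, 0.17, was at the 9.94 percentile of 10000 random gene sets. Since 2 of the genes left out were called, this excludes nothing: with TRP1 the mean was 0.26, at the 55.0 percentile, and with all 3 it was 0.38, at the 94.3 percentile, in a set that holds the genes that raised the question. It stays open. PTC7 is the direct neighbour of NMD2; whether it is carried on the plasmid was not tested.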
